A study of Mus musculus with 3 samples.

How the data were processed

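The measurement was 10x Genomics single-cell 3′ sequencing of whole dissociated tumours. Per the labels' protocols, tumour tissue was minced, digested with papain and DNase, and passed through strainers, with no sort described. The deposited values were whole-number UMI counts per gene and barcode for 2 samples, 1 sgVC and 1 sgCPT1A, and it was not known whether reads of a further sgCPT1A sample were pooled into the sgCPT1A counts, which were treated as 1 library. Per the file headers the matrices came from Cell Ranger 7.1.0, and the submitters' processing notes name Cell Ranger, Seurat 4.1.0 and GRCm38. The annotation release and the cell-calling settings were not given in the sources used here. Of 55357 gene identifiers in the files, 52081 matched GENCODE M21, which gave the coordinates printed on GRCm38. The lowest barcode had 500 UMIs in both libraries.

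The groups, filters, cell type markers, gene lists, rule for named genes and most alternatives were chosen before the data were examined. Cells were kept with at least 200 genes and at most 20% mitochondrial UMIs. This left out 280 of 9890 sgVC barcodes (94 with few genes, 277 with high mitochondrial share) and 455 of 7198 sgCPT1A barcodes (148 and 453), some failing both limits. Scrublet, run per library through scanpy, called 287 sgVC doublets (2.99%), which were left out, and 0 in sgCPT1A. A caller that marks under 0.5% of cells was treated as not having worked, so no sgCPT1A cells were left out as doublets and mixed cells can remain there.

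Both libraries were clustered together without integration (10000 UMIs per cell, log1p, 2000 variable genes chosen per library, 30 principal components, 15 neighbours, Leiden resolution 1; Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, matplotlib 3.10.9). A cluster took the class whose markers, out of 17 sets, were at least 2-fold over the median cluster and seen in at least 10% of its cells, with at least 3 markers needed. A name was withheld where another class led the top genes. These settings of the naming step were set with the data in hand, as was the removal of Rn18s, Malat1 and Xist from the variable genes. Shares have exact Clopper-Pearson 95% intervals, summed UMIs exact Poisson intervals, and ratios an interval from the exact conditional binomial, or for shares from the bounds of both. A count of 0 was given an upper limit of 3 counts.

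Within classes of at least 50 cells per library, UMIs were summed and expressed as CPM. Tumour-like cells had been planned as a main class, but with 43 sgCPT1A cells only Cpt1a and the shares of cells with Mki67 and Top2a were compared there. A list median used members with at least 20 UMIs over both libraries, and its percentile came from 10000 random lists of the same size matched over 20 bins of mean CPM. There were 33 lists, some of which share members. Named genes were the 10 highest and the 10 lowest ratios per class among genes with at least 50 UMIs, at least 50 CPM where higher and at least 25% of the highest class there, leaving out mitochondrial, ribosomal protein, predicted, haemoglobin, sex-linked, receptor segment and cell type marker genes, plus up to 4 members per list (the 2 with the highest level and the 2 with the largest ratio, with at least 50 UMIs), Cpt1a and the genes counted as shares of cells. The text names those of them that fit its groups, and some genes that met the rule are not reported here. Krt8, Krt18, Krt19, Wfdc2, Vim, Epcam, Prlr, Csn3, Tslp, Hmga2 and the RNA-quality genes Rn18s-rs5, mt-Rnr2 and Malat1 were named after their values were seen.

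The counting intervals and list percentiles were tested on simulated counts drawn from each comparison, with 200 genes changed. The counts were Poisson draws, the model the interval assumes, so coverage near 95% was built in. UMIs gathered in 1 cell, as for Il2 and Lyz1 below, were not simulated and are not covered by the intervals. The interval covered the set value for 95.9% of unchanged genes among 10174 in T-like cells, 96.4% of 8210 in dendritic-like, 96.1% of 13236 in fibroblast-like, 96.3% of 11112 in monocyte/macrophage-like and 95.9% of 9199 in neutrophil-like cells. A 4-fold change was seen with its sign in 100% of T-like, 95.5% of dendritic-like, 98.5% of fibroblast-like, 84.8% of monocyte/macrophage-like and 90.9% of neutrophil-like genes, a 2-fold change in 79.1%, 64.2%, 86.6%, 77.6% and 77.6%, and a 1.5-fold change in 65.7%, 41.8%, 67.2%, 52.2% and 59.7%. A list of 30 genes set 2-fold higher was at percentile 100 in each class. Of 40 unchanged lists, 2, 1, 3, 3 and 1 lay outside the central 95% of random lists.

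The alternatives chosen then were other cell filters (500 genes, 10% mitochondrial UMIs), doublets kept, Leiden resolution 0.5 and 2, each library clustered alone, the class from each cell's own markers, thinning to 1000 UMIs before clustering, scaling by the median ratio, equal weight per cell, only cells without UMIs of 3 neutrophil genes, and other minimums for list members. How many cells the neutrophil gene filter left is not reported here. Neutrophil genes stood at 0.951% of their neutrophil-like level in sgVC dendritic-like cells and 2.89% in sgCPT1A ones. The filter can therefore take unequal shares of the 2 libraries. Alternatives chosen after seeing the data were subtraction of free RNA (estimated per library from genes at over 500 CPM in neutrophil-like or tumour-like cells and under 10% of that elsewhere), neutrophil-like cluster 1 alone, list members at 25% or more of their highest class, shares without tumour-like cells, and gene ratios without the cell with most UMIs of the gene in each library.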

Results

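Tumours grown from 4T1, a mouse mammary carcinoma line, were profiled by droplet single-cell RNA sequencing of 3′ ends. The guide in one line was a control (sgVC) and in the other was directed at Cpt1a (sgCPT1A), the gene of the carnitine palmitoyltransferase that carries out the rate-limiting step of fatty acid entry into mitochondria. The series asks how the cell make-up of the tumour differs once Cpt1a is depleted, after an antibody against CD8 had only a limited effect on tumour regression, and its title points to cGAS-STING signalling and neutrophils. The mice were females of 8 to 10 weeks. Each group had 1 library with a file, so there were no replicates, no test was made, and every interval below covers counting error only. Of the 3 samples listed, 1 further sgCPT1A sample was not analysed here as a library of its own. It was not known whether its reads were pooled into the sgCPT1A matrix, which was treated as 1 library.

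The sgVC library held 9890 barcodes and 155948212 UMIs, with a median of 10809 UMIs and 2967.5 genes per barcode. The sgCPT1A library held 7198 barcodes and 35557125 UMIs, with a median of 2786 UMIs and 748.5 genes. After filtering, 9323 and 6743 cells were kept. Over whole libraries Rn18s-rs5 stood at 6972 CPM in sgVC and 33258 CPM in sgCPT1A, mt-Rnr2 at 5929 and 21844 CPM, and Malat1 at 3545 and 17742 CPM. These levels mix in the cell make-up: within neutrophil-like cells mt-Rnr2 stood at 15302 and 13994 CPM and Malat1 at 22201 and 25089 CPM, and within fibroblast-like cells Malat1 stood at 6329 and 10515 CPM.

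Cpt1a (ENSMUSG00000024900, chromosome 19, 3322334 to 3385733 on the plus strand of GRCm38) was measured first. In tumour-like cells it had 2111 UMIs in the sgVC library, 17.4 CPM (95% interval 16.6 to 18.1), and 22 UMIs in the sgCPT1A library, 28.5 CPM (17.9 to 43.1), a log2 ratio of 0.72 (0.04 to 1.32). That ratio compares different mixes of clusters. In cluster 21, described below, Cpt1a stood at 44.8 CPM (19.3 to 88.3; 8 UMIs) and 32.3 CPM (20.0 to 49.4; 21 UMIs), and in the other 4 tumour-like clusters at 17.3 CPM (16.6 to 18.1; 2103 UMIs) and 8.16 CPM (0.207 to 45.4; 1 UMI). The value was thus lower in the sgCPT1A library within both, but on few UMIs and with intervals that overlap, so no difference was shown within either. Cpt1a was also higher in the sgCPT1A library in neutrophil-like cells (7.92 and 15.9 CPM), monocyte/macrophage-like cells (22.8 and 43.8 CPM), T-like cells (19.5 and 30.7 CPM), fibroblast-like cells (27.8 and 46.3 CPM) and dendritic-like cells (15.4 and 29.5 CPM). A 3′ tag can lie outside the stretch a guide alters and can still count transcripts with a frameshift. Most sgCPT1A tumour-like cells also lay in a cluster that was small in sgVC, so these levels check neither the label nor the depletion.

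With tumour-like cells in the total, the largest log2 ratios of shares in the main classes were those of neutrophil-like and tumour-like cells. Neutrophil-like cells, named by S100a8, S100a9, Csf3r and G0s2, made up 19.3% of sgVC cells (18.5 to 20.1%; 1795 of 9323) and 76.0% of sgCPT1A cells (75.0 to 77.0%; 5126 of 6743), a 3.95-fold higher share (log2 ratio 1.98, 1.90 to 2.06). Tumour-like cells, named by Krt8, Krt18, Spint1 and Spint2, made up 48.0% of sgVC cells (47.0 to 49.0%; 4474 cells) and 0.638% of sgCPT1A cells (0.462 to 0.858%; 43 cells), a log2 ratio of −6.23 (−6.73 to −5.77). Monocyte/macrophage-like cells were lower, at 14.8% (14.1 to 15.5%) and 4.40% (3.93 to 4.92%). T-like cells were close, at 9.19% (8.61 to 9.80%) and 8.17% (7.53 to 8.85%), a log2 ratio of −0.17 whose interval (−0.38 to 0.04) includes 0.

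Among the smaller classes, dendritic-like cells were at 2.52% (2.21 to 2.86%) and 1.26% (1.01 to 1.56%), and NK-like cells at 0.869% (0.691 to 1.08%) and 0.460% (0.313 to 0.652%). Fibroblast-like cells were at 4.31% (3.91 to 4.74%) and 7.61% (6.99 to 8.27%), and pericyte or smooth muscle-like cells at 0.333% (0.226 to 0.472%) and 0.905% (0.693 to 1.16%). Basophil or mast cell-like cells (39 and 15), endothelial-like cells (20 and 12) and plasmacytoid dendritic-like cells (12 and 9) were few in both. Shares of all cells depend on how many tumour-like cells were captured. Of immune cells alone (4396 and 6114), neutrophil-like cells made up 40.8% (39.4 to 42.3%) and 83.8% (82.9 to 84.8%), and monocyte/macrophage-like cells 31.3% (30.0 to 32.7%) and 4.86% (4.33 to 5.43%). T-like cells made up 19.5% (18.3 to 20.7%) and 9.01% (8.31 to 9.76%) of them, dendritic-like cells 5.35% (4.70 to 6.05%) and 1.39% (1.11 to 1.72%), and NK-like cells 1.84% (1.47 to 2.29%) and 0.507% (0.345 to 0.719%). Without tumour-like cells in the total, the fibroblast-like shares were 8.29% and 7.66%, so their order turned. In that total neutrophil-like cells were at a log2 ratio of 1.05, nearer to 0 than monocyte/macrophage-like (−2.68), dendritic-like (−1.93), NK-like (−1.85) and T-like cells (−1.10). Depth per cell differed between classes and libraries: the median was 1460 and 2629 UMIs in neutrophil-like cells, 23590 and 10135 in tumour-like cells, 2863 and 4932 in T-like cells, 5586 and 5527 in monocyte/macrophage-like cells, and 14586 and 24739 in fibroblast-like cells.

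**Figure D1:**
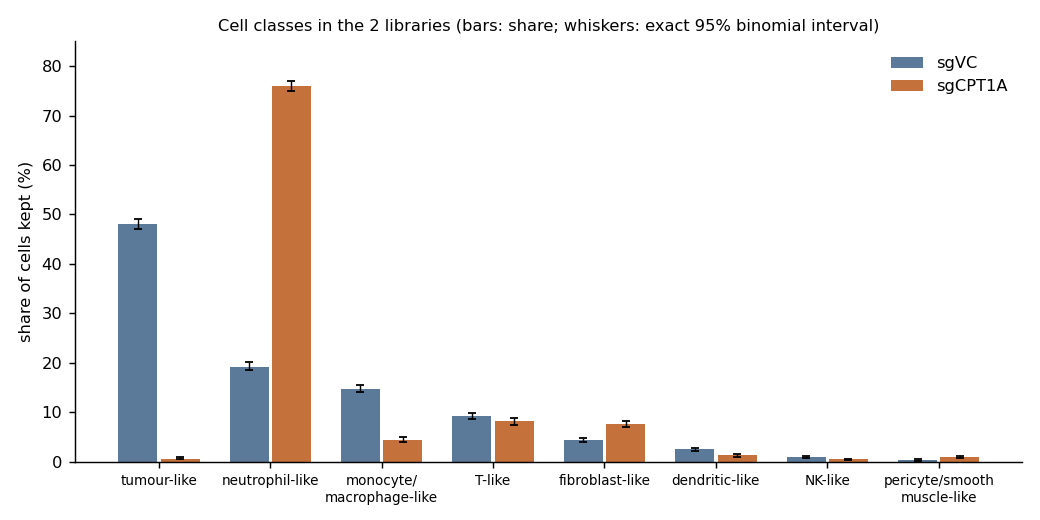
Share of kept cells (%) in 8 classes for the sgVC and sgCPT1A libraries, with exact 95% binomial intervals as whiskers. Neutrophil-like cells stand at 19.3% and 76.0%, and tumour-like cells at 48.0% and 0.638%.

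The tumour-like cells formed 5 clusters. In the 4 clusters that made up 4461 of the 4474 sgVC tumour-like cells, 94.7% of sgVC cells had a Krt8 UMI, 98.5% a Wfdc2 UMI and 99.6% a Vim UMI, while 0.0224% had a UMI of Epcam, an epithelial adhesion gene. The sgCPT1A library had 13 cells in these clusters, 38.5% of them with a Krt8 UMI. Those shares were not thinned, and the median depth was 23631 UMIs in sgVC and 2236 in sgCPT1A. In CPM, Wfdc2 (2414 and 2300) and Spint2 (242 and 220) were close. Krt8 (649 and 155), Krt18 (549 and 48.9) and Vim (3783 and 1240) were lower in the sgCPT1A cells. The other 30 tumour-like cells of the sgCPT1A library lay in cluster 21, which held 13 sgVC cells. There 100% of sgVC and 96.7% of sgCPT1A cells had an Epcam UMI. These cells differed from the other 4 clusters in more than Epcam. Vim was in 30.8% and 16.7% of them, Krt19 in 100% and 90.0%, Prlr, the prolactin receptor gene, in 76.9% and 80.0%, and Csn3, a milk casein gene, in 38.5% and 26.7%. In sgVC cells of the other 4 clusters Krt19 was in 0.314% and Prlr in 0 of 4461. Whether cluster 21 was tumour or normal mammary epithelium is left open, and the sgCPT1A share of 0.638% and the Cpt1a, Mki67 and Top2a values of the class depend on it. Without cluster 21 the tumour-like shares were 47.8% (46.8 to 48.9%) in sgVC and 0.193% (0.103 to 0.329%) in sgCPT1A. With 1 library per group and different clusters on each side, genes other than Cpt1a, Mki67 and Top2a were not compared in this class, and those 3 values compare different clusters. After thinning each cell to 1000 UMIs (45 sgVC and 5 sgCPT1A cells were shallower), 9.32% of 4429 sgVC tumour-like cells (8.48 to 10.2%) and 2.63% of 38 sgCPT1A cells (0.0666 to 13.8%) had a UMI of Mki67, a marker of dividing cells. For Top2a the shares were 19.1% (18.0 to 20.3%) and 5.26% (0.644 to 17.7%). Unthinned, the shares were 46.5% and 16.3% for Mki67 and 56.9% and 20.9% for Top2a. In neutrophil-like cells, which do not divide, the thinned shares were 0.683% and 2.32% for Mki67 and 0.615% and 0.150% for Top2a, so the sgCPT1A value of Mki67, 1 of 38 cells, could not be told from this background. Unthinned, the sgCPT1A share of 16.3% (6.81 to 30.7%) was above the 3.86% (3.35 to 4.43%) of the shallower neutrophil-like cells, and at 2000 UMIs the shares were 8.57% (1.80 to 23.1%) and 3.13% (2.59 to 3.74%).

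Gene levels were compared within the 5 classes with at least 50 cells in each library: neutrophil-like, monocyte/macrophage-like, T-like, dendritic-like and fibroblast-like. Levels are in CPM, scaled to the UMI total of the class in that library. Pairs of values give sgVC first, and log2 ratios are sgCPT1A over sgVC with the 95% interval after them. For each gene list the median log2 ratio is given with its interval and its percentile among 10000 random lists matched on level, as a description of these libraries, and members are counted as higher or lower when they differed by at least 1.5-fold.

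In neutrophil-like cells, interferon-induced genes, NF-kB targets and neutrophil attractant genes were higher in the sgCPT1A library, and genes of glycolysis, the hypoxia response and the respiratory chain were lower. Different clusters held most of the class, cluster 1 in sgVC (1559 of 1795 cells) and clusters 0, 2 and 8 in sgCPT1A (2109, 1799 and 797 of 5126), so these values compare those mixtures. The median gene had a log2 ratio of −0.34 in this class, and relative to it each log2 ratio of the whole class below is 0.34 higher. Values for cluster 1 alone, by own markers or after subtraction of free RNA were not set against a median gene. The type I interferon list had a median of 0.98 (0.90 to 1.10), percentile 100, with 24 higher, 1 lower and 9 between among 34 measured members, and 1.32 relative to the median gene. Isg15, an interferon-induced ubiquitin-like protein gene (chromosome 4, 156199424 to 156200818), stood at 2228 CPM in sgVC and 5376 CPM in sgCPT1A (1.27, 1.23 to 1.31). Rsad2, which encodes the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), stood at 915 and 3627 CPM (1.99, 1.93 to 2.05). Ifit3b (2.19, 1.91 to 2.49) was also higher, though its near copy Ifit3 can share its counts and it was at −0.70 within cluster 1, while Ifitm3 (0.09, 0.05 to 0.12) differed little. Within cluster 1 alone the list median was −0.13 (−0.26 to 0.005), so the list was not higher among cells of that cluster, where Isg15 was at 0.40 and Rsad2 at 0.72. The interferon genes could shape that cluster, which by itself makes its cells alike for them.

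The interferon gamma list, with a median of 0.51 (0.43 to 0.61), percentile 99.97, and 0.27 (0.16 to 0.36) within cluster 1 alone, included Gbp5 (214 and 661 CPM, log2 1.63, 1.51 to 1.75), a guanylate-binding protein gene, and Cxcl9 (2.18, 1.83 to 2.54). Cd274 (1777 and 2524 CPM, log2 0.51, 0.46 to 0.55), the gene of the checkpoint ligand PD-L1, was higher too. Of the 9 measured cGAS-STING pathway genes, 4 were higher, 1 lower and 4 between, with a median of 0.51 (0.28 to 0.86) and percentile 99.08. Ikbke (1.93, 1.64 to 2.23), a kinase of the interferon-inducing pathway, and Cxcl10 (693 and 1902 CPM, log2 1.46, 1.39 to 1.52) were higher and Samhd1 (0.12, 0.05 to 0.19) was close. The 16 NF-kB targets split into 9 higher, 0 lower and 7 between, with a median of 0.76 (0.71 to 0.79) and percentile 100. Tnip1 (1.47, 1.30 to 1.66), Traf1 (1.32, 1.21 to 1.42), Tnf (1166 and 2435 CPM, log2 1.06, 1.01 to 1.11) and Cxcl2 (0.52, 0.51 to 0.53) were higher, with Traf1 at 0.53 and Tnf at 0.48 within cluster 1. Il1b (−0.08, −0.09 to −0.07), the interleukin-1 beta gene, was slightly lower in CPM but higher by 0.26 relative to the median gene. Ccl3 (0.93, 0.91 to 0.94), Ccl4 (1.02, 0.99 to 1.04), Il1a (1425 and 3710.5 CPM, log2 1.38, 1.33 to 1.43) and Csf3 (55.4 and 301 CPM, log2 2.44, 2.21 to 2.69), the gene of granulocyte colony-stimulating factor, were higher among neutrophil attractants and growth factors (median 0.64, 0.49 to 0.97, percentile 99.88). Over the alternatives Ccl3 ran from 0.76 to 1.91, Ccl4 from 0.60 to 1.94, Il1a from 1.11 to 2.37 and Csf3 from 1.26 to 2.79. Monocyte and lymphocyte attractants split: Cxcl11 (2.22, 1.99 to 2.46), like Cxcl9 and Cxcl10 a CXCR3 ligand gene, was higher, and Ccl6 (−1.17, −1.25 to −1.10) was lower, though at −0.0123 within cluster 1. Their median was 0.50 (0.15 to 0.86), percentile 99.82, with 5 higher, 5 lower and 1 between, and turned to −0.11 over members with at least 1 UMI. With cells named by their own markers the medians lay further from 0, at 1.32 for interferon gamma, 1.44 for NF-kB and 0.92 for cGAS-STING genes. That naming gave 1975 rather than 1795 sgVC neutrophil-like cells and 3949 rather than 4474 sgVC tumour-like cells. The sgVC neutrophil-like class then held 73 Cpt1a UMIs at 12.1 CPM, rather than 22 at 7.92 CPM, so cells with far more UMIs had joined it. Values by own markers here and below therefore compare another set of cells.

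Genes listed for antitumour neutrophils had a median of 0.83 (0.69 to 0.98, percentile 99.97) and those for protumour neutrophils 0.21 (0.09 to 0.35, percentile 95.68). The former was at 1.47 by own markers, and the latter turned to −0.14 over members with at least 1 UMI and was 0.55 relative to the median gene. The protumour list held both Ptgs2 (1873 and 3386 CPM, log2 0.85, 0.81 to 0.90), the cyclooxygenase-2 gene, and Wfdc17 (4418 and 1056 CPM, log2 −2.07, −2.10 to −2.03). The SiglecF-high neutrophil list had a median of −0.13 (−0.24 to 0.13), percentile 49.01, which was 0.21 relative to the median gene, and Siglecf itself had a UMI in 0.223% (0.0607 to 0.570%) of sgVC and 0.0585% (0.0121 to 0.171%) of sgCPT1A cells. The secondary and tertiary granule list had a median of −0.31 (−0.41 to −0.22), which was 0.03 relative to the median gene, with 3 higher, 5 lower and 3 between. Over its 9 members at 25% or more of their highest class the median was −0.91 (−1.11 to −0.73), and within cluster 1 alone −0.71. Lcn2 (2092 and 6706 CPM, log2 1.68, 1.64 to 1.72) was higher, while Mmp8 (114 and 23.3 CPM, log2 −2.29, −2.52 to −2.07), the neutrophil collagenase gene, Cd177 (−2.38, −2.82 to −1.94) and Anxa1 (−2.26, −2.40 to −2.12) were lower, Mmp8 at −0.96 within cluster 1. Cd177 ran from −2.60 to −1.37 over the alternatives. Cybb (159 and 366 CPM, log2 1.21, 1.07 to 1.35), the catalytic subunit of the phagocyte oxidase, was higher in an oxidative burst list with a median of 0.20 (0.12 to 0.38, percentile 88.16), which was −0.18 within cluster 1 alone.

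Metabolic lists were lower in neutrophil-like cells of the sgCPT1A library. Glycolysis had a median of −0.68 (−0.74 to −0.60, percentile 0.66, with 1 higher, 8 lower and 6 between), with Gapdh (2739 and 1021 CPM, log2 −1.42, −1.46 to −1.38) and Gpi1 (−1.98, −2.10 to −1.85). The hypoxia list had a median of −0.65 (−0.77 to −0.58, percentile 1.63, with 0 higher, 8 lower and 6 between), with Bnip3 (−1.46, −1.56 to −1.36), Ankrd37 (−1.61, −1.78 to −1.43) and Hilpda (−0.55, −0.59 to −0.51), the last at 0.39 when cells were named by their own markers, and Bnip3 at −0.58 within cluster 1. Outside that list Egln1 (−2.33, −2.55 to −2.10), an oxygen-sensing prolyl hydroxylase gene, and Fam162a (1166 and 223 CPM, log2 −2.39, −2.46 to −2.31) were lower too. Nuclear genes of oxidative phosphorylation had a median of −0.74 (−0.84 to −0.55, percentile 0.23, with 0 higher, 21 lower and 16 between) and mitochondrially encoded genes −0.98 (−1.10 to −0.88, percentile 0.19), with mt-Cytb (−1.44, −1.52 to −1.36) and mt-Co1 (−1.21, −1.32 to −1.10). The nuclear list was at −0.41 after subtraction of free RNA and −0.40 relative to the median gene, and over its 4 members at 25% or more of their highest class at −0.35 (−0.46 to −0.25), close to the median gene. In this class the subtraction changed the sgVC counts alone. With cells named by their own markers it was at −2.94, and mt-Cytb at −2.86. Within cluster 1 the mitochondrially encoded list was at −0.64. Fatty acid oxidation genes had a median of −0.91 (−1.16 to −0.48, percentile 0.5), but most members were at low levels in this class, and over those at 25% or more of their highest class the median was 0.17, against −2.63 with cells named by their own markers. Further large ratios in the class were those of Thbs1 (9.71 and 124 CPM, log2 3.67, 3.12 to 4.27), the thrombospondin 1 gene, Acp5 (3.58, 2.90 to 4.37), Hook2 (2.54, 2.29 to 2.81), Hal (2.33, 1.99 to 2.70), Sh3bp5 (2.31, 1.90 to 2.74) and Abcc5 (2.24, 1.76 to 2.76), all higher. Thbs1 was at 0.94 with cells named by their own markers, and within cluster 1 alone Acp5 was at 1.57, Hal at 0.73 and Abcc5 at 0.64. Scimp (−2.99, −3.28 to −2.71), Gsn (−2.78, −2.94 to −2.61), the gelsolin gene, and Igfbp6 (−2.57, −2.72 to −2.42) were lower. So were Fosb (−2.25, −2.37 to −2.13) and Zfp36l2 (−2.18, −2.29 to −2.08).

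Shares of neutrophil-like cells with a UMI, after thinning to 500 UMIs (no cell was shallower in either library), were 52.6% (50.3 to 54.9%) and 76.3% (75.1 to 77.5%) for Isg15 and 51.0% (48.6 to 53.3%) and 62.6% (61.3 to 64.0%) for Cd274. For Cxcr2, the receptor gene for neutrophil chemokines, they were 15.4% (13.8 to 17.2%) and 17.0% (16.0 to 18.1%). Unthinned, they were 74.8% and 92.4% for Isg15, 75.8% and 89.0% for Cd274, 35.4% and 42.2% for Cxcr2, and 0.724% and 0.468% for Siglecf. In fibroblast-like cells thinned alike, Isg15 was in 9.45% and 8.58% and Cd274 in 2.49% and 2.73% of cells. Cxcr2 was in 0 of 402 sgVC fibroblast-like cells, which allows up to 0.746%, and in 0.390% of sgCPT1A cells. Siglecf was in 0 of 402 and 0 of 513, which allows up to 0.746% and 0.585%, so its neutrophil-like shares could not be told from background.

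**Figure D2:**
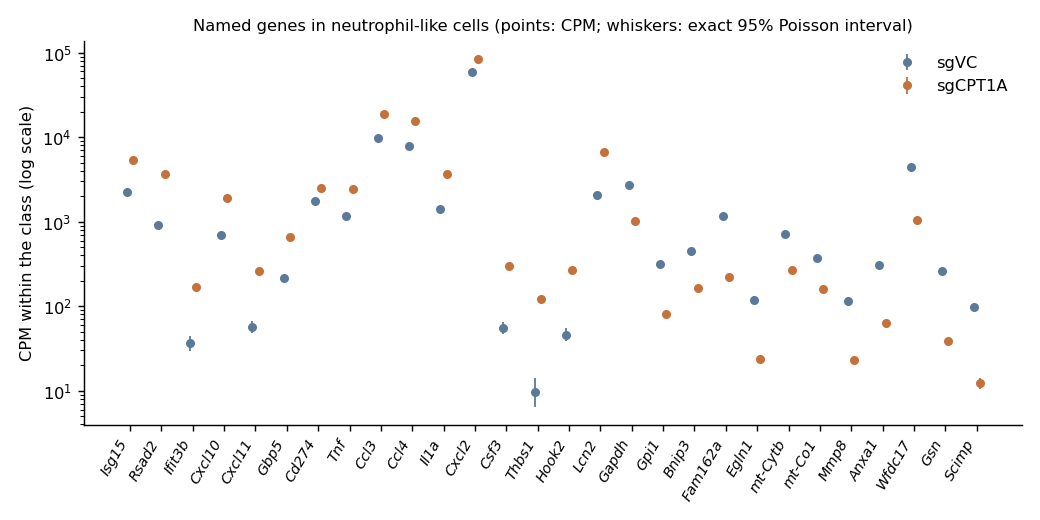
CPM (log scale) of 28 named genes in neutrophil-like cells of the sgVC and sgCPT1A libraries, with exact 95% Poisson intervals as whiskers. Isg15 stands at 2228 and 5376 CPM and Gapdh at 2739 and 1021 CPM.

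In monocyte/macrophage-like cells (1377 and 297), interferon-induced genes were again higher in the sgCPT1A library, while genes of cell division, cholesterol synthesis and MHC class II presentation were lower. Cluster 6 held 919 of the sgVC cells and cluster 9 held 205 of the sgCPT1A cells, so here too different clusters held most of the class. The type I interferon list had a median of 0.96 (0.92 to 1.10, percentile 100, with 29 higher, 0 lower and 8 between of 37), with Isg15 (0.87, 0.79 to 0.95) and Isg20 (2.79, 2.42 to 3.16), the last at 2.37 with equal weight per cell and 6.86 after subtraction of free RNA. Yet Ifnb1 (307 and 28.0 CPM, log2 −3.45, −3.85 to −3.09), the interferon beta gene itself (chromosome 4, 88522025 to 88522774), was lower, at −2.15 without cells holding neutrophil UMIs. The interferon-induced chemokine genes Cxcl9 (−1.77, −1.96 to −1.59) and Cxcl10 (−1.11, −1.18 to −1.04) were lower too. All 7 MHC class II presentation genes were lower by at least 1.5-fold (median −1.06, −1.11 to −0.97, percentile 0.2). Among them were Cd74 (5846 and 3333 CPM, log2 −0.81, −0.85 to −0.78), the invariant chain, H2-Aa (−0.95, −1.0 to −0.91), H2-DMb1 (−1.48, −1.63 to −1.34) and H2-DMa (−1.34, −1.46 to −1.22). Without cells holding neutrophil UMIs the list was at −0.63 and Cd74 at −0.32. The cholesterol synthesis list had a median of −1.40 (−2.10 to −1.27, percentile 0, with 0 higher, 14 lower and 2 between), led by Fdps (94.5 and 6.53 CPM, log2 −3.86, −4.73 to −3.10), the farnesyl diphosphate synthase gene (chromosome 3, 89093588 to 89101959). In contrast, Insig1 (0.05, −0.19 to 0.29) differed little. The cell cycle list had a median of −1.68 (−1.86 to −1.48, percentile 0, with 0 higher, 31 lower and 1 between). Stmn1 (−1.82, −2.30 to −1.37) was lower, and Tk1, the thymidine kinase gene, had 110 UMIs in sgVC and 0 in sgCPT1A, at least 8.30-fold lower when set against 3 UMIs.

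Among the largest ratios in these cells, Ptges (9.29 and 205 CPM, log2 4.46, 4.13 to 4.81), the prostaglandin E synthase gene, Nos2 (51.6 and 372 CPM, log2 2.85, 2.68 to 3.01), the inducible nitric oxide synthase gene, and Cd200 (4.96, 4.32 to 5.66) were higher in the sgCPT1A library. So were Jag1 (3.06, 2.64 to 3.49), a Notch ligand gene, Cxcl3 (272 and 2211 CPM, log2 3.02, 2.95 to 3.09) and Lpl (3.09, 2.81 to 3.39). Without cells holding UMIs of 3 neutrophil genes, Cxcl3 was at 0.64, Lpl at 0.76 and Ptges at 2.47, and Cd200 was at 2.80 with equal weight per cell. Neutrophil genes stood at 2.86% of their neutrophil-like level in sgVC and 5.72% in sgCPT1A cells of this class. The neutrophil granule list was higher too, with a median of 1.56 (1.26 to 2.0, percentile 100, with 6 higher, 1 lower and 1 between of 8), and 1.84 after subtraction of free RNA. Pdpn (2.83, 2.63 to 3.03), Cacna1d (2.53, 2.16 to 2.90) and Cfb (2.45, 2.15 to 2.75), the complement factor B gene, were higher as well. Over the alternatives Pdpn ran from 1.82 to 2.85, Cacna1d from 1.84 to 2.55 and Cfb from 2.18 to 2.87. Mgl2 (433 and 4.20 CPM, log2 −6.69, −7.82 to −5.76), a C-type lectin gene of macrophages and dendritic cells (chromosome 11, 70130329 to 70137550), and Ccl24 (807 and 106 CPM, log2 −2.92, −3.12 to −2.73), an eosinophil attractant gene, were lower, Mgl2 at −3.79 with cells named by their own markers. Ccl24 ran from −3.17 to −2.01 over the alternatives. Lower genes also included Cd81 (−2.47, −2.91 to −2.06), Lair1 (−2.25, −2.69 to −1.84), Apex1 (−2.19, −2.79 to −1.64), Aldoc (−2.10, −2.72 to −1.54), Dtymk (−2.07, −2.53 to −1.65) and Gas6 (−2.01, −2.60 to −1.47). Lyz1 also met the rule (4.88, 4.48 to 5.30), but 98% of its sgCPT1A UMIs were in 1 cell, and without the cell with most UMIs in each library its log2 ratio was 0.41. Arg1 (1823 and 3454 CPM, log2 0.92, 0.88 to 0.96), the arginase gene, Pf4 (1.08, 1.04 to 1.12) and Apoe (0.44, 0.41 to 0.47) were higher, though without cells holding neutrophil UMIs they were at 0.32, −0.32 and −0.0290, and the protumour list had a median of 0.86 (0.73 to 0.95, percentile 100). Alternatively activated and lipid macrophage genes (0.10, −0.06 to 0.33, percentile 85.01) and inflammatory macrophage genes (−0.24, −0.37 to −0.09, percentile 24.58) lay within the range of random lists. Over its 12 members at 25% or more of their highest class the former was at 0.53 (0.47 to 0.55), above that range, and over members with at least 1 UMI at −0.25.

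In T-like cells (857 and 551; cluster 7 held most in both libraries, 504 and 429), interferon-induced genes were higher, and cell cycle and cholesterol synthesis genes were lower in the sgCPT1A library. Several cytokine genes were lower, while Csf1 and Cd40lg were higher, as single named genes and not as a list. The share of T-like cells with a Cd8a UMI was 11.3% (9.14 to 13.7%) in sgVC and 5.42% (3.63 to 7.73%) in sgCPT1A, and with a Cd8b1 UMI 13.4% (11.1 to 16.0%) and 6.77% (4.76 to 9.29%), after thinning to 1000 UMIs (76 and 34 cells were shallower). Cd4 was in 14.1% (11.7 to 16.7%) and 17.2% (14.1 to 20.8%), and Foxp3, the regulatory T cell factor, in 2.43% (1.47 to 3.77%) and 1.16% (0.427 to 2.51%). Unthinned, the shares were 20.4% and 12.2% for Cd8a, 23.1% and 13.6% for Cd8b1, 34.2% and 50.1% for Cd4, and 7.0% and 5.26% for Foxp3. In fibroblast-like cells thinned alike, Cd4 was in 0.255% and 0.198%, Cd8a in 0 of 392 (up to 0.765%) and 0.198%, and Cd8b1 and Foxp3 in 0 of 392 and 0 of 505 (up to 0.765% and 0.594%). In NK-like cells Ncr1 was in 33.3% (23.1 to 44.9%) of 78 and 29.0% (14.2 to 48.0%) of 31 cells with 3 and 0 cells left out, and in 66.7% and 71.0% unthinned, against 0 of 392 and 0 of 505 fibroblast-like cells.

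The type I interferon list had a median of 0.67 (0.58 to 0.77) in T-like cells (percentile 100, with 21 higher, 0 lower and 14 between of 35), and 0.37 after subtraction of free RNA. Neutrophil genes stood at 0.360% of their neutrophil-like level in sgVC T-like cells and 4.05% in sgCPT1A T-like cells, so genes abundant in neutrophils, Isg15 and Rsad2 among them, are not named here. The cholesterol list was lower, with a median of −1.09 (−1.29 to −0.87, percentile 0, with 0 higher, 10 lower and 6 between). Among the lower genes were Cyp51 (−1.94, −2.36 to −1.53), Fdps (−1.78, −2.25 to −1.34) and Idi1 (−1.72, −2.16 to −1.31). The cell cycle list had a median of −0.72 (−0.85 to −0.63, percentile 0, with 0 higher, 18 lower and 14 between), with Aurkb (−1.59, −2.05 to −1.15), a mitotic kinase gene, and, outside the list, Cdc20 (−1.65, −2.08 to −1.25). Ccl5 (2599 and 964 CPM, log2 −1.43, −1.49 to −1.37), Ccl1 (−3.60, −4.02 to −3.19), Csf2 (−1.62, −1.80 to −1.44) and Lta (−1.84, −2.29 to −1.41) were lower cytokine and chemokine genes. Il13 (−1.78, −2.05 to −1.52) and Il2 (−4.22, −4.76 to −3.73) were lower as well. However, 1 cell held 89% of the sgVC Il2 UMIs and without the cell with most UMIs in each library the Il2 log2 ratio was −1.54, and −1.28 without cells holding neutrophil UMIs. Higher in the sgCPT1A library were Lag3 (17.5 and 51.6 CPM, log2 1.56, 1.13 to 2.01), a checkpoint receptor gene, Cd40lg (1.40, 1.07 to 1.72), and Csf1 (1.54, 1.30 to 1.79). Kdm6b (1.27, 1.12 to 1.41), H60b (1.25, 0.98 to 1.53), Mylip (1.51, 1.13 to 1.90) and Abcg1 (1.23, 0.86 to 1.60) were higher as well. Lists of cytotoxic genes (−0.12, −0.25 to −0.01, percentile 32.62), checkpoint genes (−0.04, −0.09 to 0.19, percentile 53.01) and regulatory T cell genes (−0.43, −0.51 to −0.35, percentile 3.17) lay within or near the range of random lists, and with doublets kept cytotoxic genes were at 0.50, checkpoint genes at 0.65 and regulatory T cell genes at 0.25. Ctla4 (−0.06, −0.16 to 0.05) was close, whereas naive and memory genes had a median of 0.52 (0.26 to 0.61, percentile 99.73). Among them Il7r (0.55, 0.41 to 0.69) was higher by less than 1.5-fold, and Klf2 (−0.59, −0.69 to −0.49) was lower.

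In dendritic-like cells (235 and 85; cluster 13 held most in both libraries, 148 and 60), interferon-induced genes were higher, and genes of cholesterol synthesis, cell division and glycolysis were lower in the sgCPT1A library. Type I interferon genes had a median of 0.52 (0.33 to 0.68, percentile 100, with 16 higher, 1 lower and 17 between), and 0.28 after subtraction of free RNA. Irf7 (52.3 and 199 CPM, log2 1.93, 1.57 to 2.29), a factor of interferon production, and Ifi27l2a (1.76, 1.61 to 1.91) were higher. Cholesterol synthesis genes had a median of −1.74 (−2.05 to −1.41, percentile 0), with Idi1 (−2.20, −2.79 to −1.66) and Msmo1 (−2.57, −3.82 to −1.54), and cell cycle genes −1.68 (−2.07 to −1.46, percentile 0), with Cenpa (−1.68, −2.45 to −0.98). The cell cycle list was at −0.84 without cells holding neutrophil UMIs, −0.98 over members at 25% or more of their highest class and −2.24 with doublets kept. Glycolysis genes were lower too, with a median of −0.91 (−1.04 to −0.78, percentile 0, with 0 higher, 12 lower and 3 between), among them Pgk1 (−1.44, −1.70 to −1.19) and Tpi1 (−1.35, −1.65 to −1.06). The lower genes included Ccl17 (622 and 38.5 CPM, log2 −4.01, −4.55 to −3.52), a chemokine gene of migratory dendritic cells, Plet1 (−2.24, −2.55 to −1.94), Cd209e (−3.76, −5.66 to −2.36), Slc27a3 (−2.66, −3.75 to −1.74) and Eif4ebp1 (−2.05, −2.82 to −1.37), Ccl17 running from −5.57 to −2.52 over the alternatives. Plet1 ran from −3.02 to −1.18 over them and Slc27a3 from −3.05 to −1.61. Il12b (−1.13, −1.54 to −0.73), the interleukin-12 subunit gene, and Ifnb1 (−1.22, −1.60 to −0.86) were lower too, though Il12b was at 0.51 without cells holding neutrophil UMIs and Ifnb1 at −0.40 by own markers. The higher genes included Abcg1 (1.88, 1.38 to 2.38), Foxp1 (1.80, 1.42 to 2.19), Ffar2 (2.33, 1.61 to 3.09), Fam43a (2.48, 1.70 to 3.31), Ppp1r16b (2.07, 1.33 to 2.83) and Txndc5 (2.11, 1.72 to 2.5), the last at −0.18 with cells named by their own markers. Fam214a also met the rule (3.60, 2.56 to 4.81), with 73% of its sgCPT1A UMIs in 1 cell and a log2 ratio of 1.89 without such cells and 1.02 by own markers. Naming by own markers gave 225 and 56 dendritic-like cells rather than 235 and 85. B-like cells had no class of their own in the main setting, and whether they lay in this class was not determined. Dendritic cell activation genes (0.00, −0.29 to 0.08, percentile 65.79) and MHC class II genes (0.08, 0.03 to 0.13, percentile 79.19) differed little, but both depended on how cells were named, at 0.37 and 0.65 by own markers, and activation genes were at −0.35 (−0.48 to −0.10) after subtraction of free RNA.

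In fibroblast-like cells (402 and 513; cluster 10 held most in both libraries, 321 and 310), the type I interferon list had a median near 0, while interferon gamma, monocyte and lymphocyte attractant and cholesterol synthesis genes were lower in the sgCPT1A library. The type I list had a median of 0.00 (−0.18 to 0.11, percentile 79.48, with 5 higher, 7 lower and 23 between of 35), and −0.21 (−0.38 to −0.11) after subtraction of free RNA. Ifit1 (−1.59, −1.73 to −1.45) was lower. The interferon gamma list was lower, with a median of −0.72 (−0.84 to −0.51, percentile 0, with 0 higher, 10 lower and 9 between), including Iigp1 (−0.92, −1.0 to −0.84) and Gbp4 (−2.11, −2.39 to −1.82). Over the alternatives Ifit1 ran from −1.90 to −0.81, Iigp1 from −0.95 to −0.23 and Gbp4 from −2.40 to −1.65. Monocyte and lymphocyte attractants were lower too (median −1.24, −1.34 to −1.10, percentile 0). Among them were Cxcl10 (1368 and 597 CPM, log2 −1.20, −1.24 to −1.15), Ccl2 (3074 and 1889.6 CPM, log2 −0.70, −0.73 to −0.67), the main monocyte attractant gene, and Ccl7 (−1.0, −1.04 to −0.96). Neutrophil attractants and growth factors were higher, with a median of 0.71 (0.65 to 0.78, percentile 100, with 8 higher, 2 lower and 4 between), but at −0.67 after subtraction of free RNA. With cells named by their own markers the interferon gamma list was at −0.29 and the monocyte and lymphocyte attractants at −0.41, among them Cxcl10 at −0.44, Ccl7 at −0.30 and Ccl2 at −0.22. That naming gave 702 rather than 402 sgVC fibroblast-like cells, so these values compare another set of cells. Those attractants were at −0.85 over 6 members at 25% or more of their highest class. MHC class I genes had a median of −0.46 (−0.61 to −0.40, percentile 0.18), with H2-D1 (−0.46, −0.48 to −0.43). All 16 cholesterol synthesis genes were lower by at least 1.5-fold, with a median of −1.62 (−1.79 to −1.38) and percentile 0, Sqle (−2.81, −3.23 to −2.41) among them. The cell cycle list had a median of −0.84 (−1.01 to −0.79, percentile 0, with 0 higher, 31 lower and 1 between) and glycolysis −0.64 (−0.70 to −0.57, percentile 0.03), with Gapdh (−1.08, −1.12 to −1.04) and Pgk1 (−1.17, −1.25 to −1.10). Higher genes included Apod (46.0 and 199.6 CPM, log2 2.12, 1.94 to 2.30), Mfap4 (2.10, 1.97 to 2.24), Itih5 (2.10, 1.92 to 2.29), and Clec3b (2.07, 1.91 to 2.24). Further higher genes were Smoc2 (1.84, 1.52 to 2.17), Hmcn1 (1.82, 1.52 to 2.14), Pamr1 (1.98, 1.66 to 2.32), Dpep1 (1.82, 1.55 to 2.11) and Selenop (1.92, 1.77 to 2.08). Crabp1 (1047 and 142 CPM, log2 −2.88, −2.96 to −2.80), a retinoic acid binding protein gene (chromosome 9, 54764748 to 54773110), Aldh1a2 (−2.80, −3.08 to −2.52), which makes retinoic acid, and Il11 (−2.28, −2.43 to −2.13) were lower. Also lower were Cryab (−2.21, −2.34 to −2.07), Col6a5 (−1.97, −2.19 to −1.76), Ch25h (−1.96, −2.23 to −1.69) and Rgcc (−1.95, −2.08 to −1.81).

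Mitochondrially encoded genes, a sign of RNA quality and cell state, went the other way from neutrophil-like cells in the other classes, with medians of 0.58 (0.52 to 0.73) in T-like, 1.05 (0.95 to 1.25) in dendritic-like, 0.55 (0.42 to 0.63) in monocyte/macrophage-like and 1.39 (0.96 to 1.44) in fibroblast-like cells, the last at 0.70 by own markers. The nuclear RNA 7SK was higher in the sgCPT1A library in T-like (3.17, 2.91 to 3.43), dendritic-like (2.88, 2.52 to 3.25) and fibroblast-like cells (2.84, 2.72 to 2.96). Rn18s-rs5 stood at 17207 and 44194 CPM in T-like, 11644 and 31437 CPM in dendritic-like, 9992 and 27354 CPM in fibroblast-like, 16355 and 48761 CPM in monocyte/macrophage-like and 13838 and 27209 CPM in neutrophil-like cells. The dissociation stress list, a sign of sample handling, had medians of −0.16 (−0.21 to −0.14) in neutrophil-like (0.18 relative to the median gene), 0.04 (−0.04 to 0.14) in monocyte/macrophage-like, 0.27 (0.24 to 0.31) in T-like, 0.14 (0.06 to 0.25) in dendritic-like and −0.09 (−0.10 to 0.02) in fibroblast-like cells. These lay within the random range in 4 of 5 classes (percentile 99.5 in T-like cells).

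**Figure D3:**
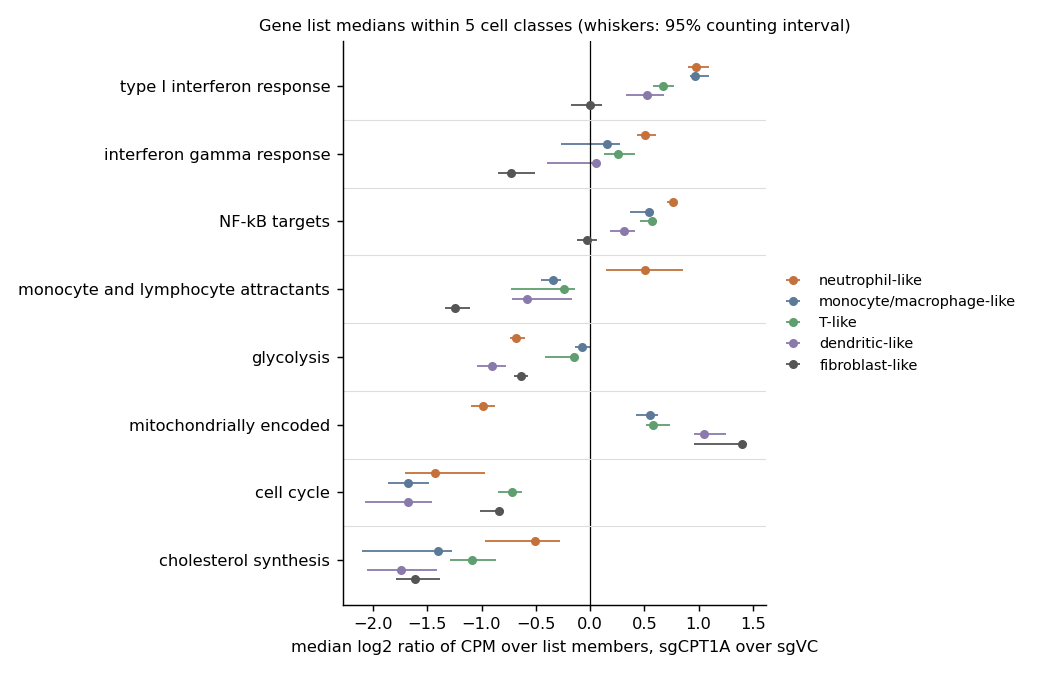
Median log2 ratio of CPM (sgCPT1A over sgVC) of 8 gene lists in 5 cell classes, with 95% counting intervals as whiskers. Cholesterol synthesis lies between −1.74 and −1.09 in the 4 classes other than neutrophil-like, and the type I interferon list is at 0.98 in neutrophil-like and 0.00 in fibroblast-like cells.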

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

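Which tests to weigh in this part was chosen only after the result was seen, though the scaling and the other ways of naming cells had been set before the data were examined. The low share of tumour-like cells in the sgCPT1A library was not made by the cell filter: if each barcode left out had been tumour-like, the share would be 6.92%, against a lower bound of 47.0% in sgVC. Nor did another way of naming cells bring them back, since the largest share over 5 such ways was 0.623% (0.449 to 0.841%; 42 cells). That test was first run as the log2 ratio of shares nearest to 0, which was −4.44, and was replaced because clustering each library alone left 1999 sgVC cells unnamed. Both versions spoke against this explanation for cells that express the tumour markers. All 5 ways used the same marker set, so tumour cells low in those genes would have been missed. Sampling of the tumour or the yield of tumour cells could not be told from an effect of the guide, because the group had 1 library with a file, so a loss of tumour cells in these tumours is possible but was not shown.

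The higher type I interferon list in neutrophil-like cells of the sgCPT1A library was not made by scaling, since its median relative to the median gene was 1.32 (1.24 to 1.44). Another mix of neutrophil-like states could not be told apart from a response within states. In 4 clusters made without the interferon genes the list median ran from −0.27 to 1.01, and a further 7 of 11 clusters, with 142 sgVC and 3876 sgCPT1A cells, had too few cells in one library. The 4 medians were −0.27 (−0.39 to −0.06), 0.13 (−0.08 to 0.33), 0.59 (0.32 to 0.79) and 1.01 (0.69 to 1.24). In the first clustering the medians were 0.05 in cluster 0, −0.13 in cluster 1, 0.46 in cluster 2 and 0.32 in cluster 8. Interferon genes could shape those first clusters, which by itself makes cells within a cluster alike for them. How much of the difference came from which states were present was thus not decided, and a cluster that is mostly 1 library may be that library.

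Lower cholesterol synthesis and cell cycle lists in T-like, dendritic-like, monocyte/macrophage-like and fibroblast-like cells were not made by free RNA of tumour-like cells in the sgVC library. After subtraction the medians nearest to 0 were those of T-like cells, −1.03 (−1.29 to −0.76) for cholesterol synthesis and −0.63 (−0.78 to −0.55) for cell cycle. Scaling did not make them either, with −1.04 (−1.24 to −0.82) and −0.67 (−0.80 to −0.58). These lists were not compared within clusters, so another mix of cells within a class was not tested. Doublets were left out of the sgVC library alone, and any that were not called can remain. With doublets kept the cell cycle list was lower still in fibroblast-like (−1.56) and dendritic-like cells (−2.24), while cholesterol synthesis was less low in dendritic-like cells (−1.33). A shared cause such as a poorer or more inflamed tissue, or a difference in handling between the 2 samples, may lie behind both lists, and with 1 library per group neither cause could be tested.

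Some lists stood at opposite ends in different classes, and the cause was not tested. The interferon gamma list was 1.23 higher in neutrophil-like (0.51) than in fibroblast-like cells (−0.72). The list of monocyte and lymphocyte attractants was 1.74 higher in neutrophil-like than in fibroblast-like cells. Mitochondrially encoded genes were higher than in neutrophil-like cells by 1.57 in T-like, 2.03 in dendritic-like, 2.38 in fibroblast-like and 1.54 in monocyte/macrophage-like cells. These differences depended on how lists and cells were taken, since the attractants in neutrophil-like cells were at −0.11 over members with at least 1 UMI, and mitochondrially encoded genes in fibroblast-like cells at 0.70 by own markers. Within neutrophil-like clusters 0, 1, 2 and 8 the mitochondrially encoded list was at −0.25, −0.64, −0.38 and −0.10 (−0.70 to 0.18), against −0.98 for the class. In the clusters made without the interferon genes it was at −0.41, −1.18, −0.04 and −1.94. How much of the class value came from the mix of clusters was not decided.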

How the results depend on the processing

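Some of the tests in this part, named here as added, were chosen only after the result was seen. No paired analysis was possible because each group had 1 library with a file. Values are log2 ratios or list medians, the cause was not tested, and values not given stayed within the counting interval or concern results other than the main ones. The neutrophil-like share of all cells (1.98) was 1.86 with the class from own markers, 2.42 with at least 500 genes and 2.17 after thinning. The tumour-like share (−6.23) was −4.44 with each library clustered alone, where monocyte/macrophage-like cells were at −1.48 and dendritic-like cells at −2.79. Dendritic-like cells were at −1.54 and fibroblast-like cells at 0.20 by own markers. With tumour-like cells left out of the total (added), neutrophil-like cells were at 1.05, monocyte/macrophage-like at −2.68, T-like at −1.10, dendritic-like at −1.93, NK-like at −1.85 and fibroblast-like at −0.11, the only class share whose direction turned. The Cpt1a ratio in tumour-like cells stayed within its interval in all 3 alternatives. For the type I interferon list, neutrophil-like cells were at 1.32 relative to the median gene, 1.67 by own markers and −0.13 in cluster 1 alone (added). The last value had the other sign, but its interval (−0.26 to 0.005) includes 0. Monocyte/macrophage-like cells were at 0.79 with equal weight per cell, 0.88 with doublets kept and 1.20 without cells holding neutrophil UMIs. T-like cells were at 0.57 over members at 25% or more of their highest class (added), 0.57 with equal weight, 0.85 with doublets kept, 0.51 by own markers and 0.37 after subtraction of free RNA (added). Dendritic-like cells were at 0.31 over members with 100 UMIs, 0.83 with doublets kept, 0.94 with at least 500 genes and 0.28 after subtraction, and fibroblast-like cells at −0.21 after subtraction. Cholesterol synthesis in dendritic-like cells was at −1.33 with doublets kept, −1.33 by own markers and −2.21 without cells holding neutrophil UMIs. For cell cycle, T-like cells were at −0.61 over members with 100 UMIs, −1.11 with equal weight, −1.04 with doublets kept and −1.02 without cells holding neutrophil UMIs. Dendritic-like cells were at −0.98 over members at 25% or more (added), −1.18 with equal weight, −2.24 with doublets kept, −1.44 with at least 500 genes, −1.36 by own markers, −0.84 without cells holding neutrophil UMIs and −1.44 after subtraction. Fibroblast-like cells were at −0.74 scaled, −1.06 with equal weight, −1.56 with doublets kept, −1.13 by own markers, −1.37 without cells holding neutrophil UMIs and −0.66 after subtraction. Monocyte/macrophage-like cells were at −1.93 over members at 25% or more and −1.89 without cells holding neutrophil UMIs. Of 1216 alternative values of genes and 540 of list medians, 397 and 143 lay outside the counting interval, besides those that turned direction. A turn was counted only where the interval of the main value did not include 0, whether or not the interval of the alternative did. Among 152 genes, 8 turned direction under an alternative. In neutrophil-like cells these were Il1b (0.26 scaled, 0.91 by own markers), Hilpda (0.39 by own markers), Ifit3b (−0.70) and Ifitm3 (−0.59), the latter 2 in cluster 1 alone. Without cells holding neutrophil UMIs, Il12b in dendritic-like cells was at 0.51, and Pf4 at −0.32 and Apoe at −0.0290 in monocyte/macrophage-like cells. Txndc5 in dendritic-like cells was at −0.18 by own markers. Among 54 list medians, 11 turned direction, counting the interferon list in cluster 1 alone. In T-like cells with doublets kept, cytotoxic genes were at 0.50 and regulatory T cell genes at 0.25. MHC class II genes in dendritic-like cells were at −0.0107 with equal weight. Neutrophil attractants in fibroblast-like cells were at −0.0351 over members at 25% or more (added), −0.33 without cells holding neutrophil UMIs and −0.67 after subtraction (added). In neutrophil-like cells the dissociation list was at 0.18 scaled, granules at 0.0303 scaled and 0.13 by own markers, fatty acid oxidation at 0.17 over members at 25% or more (added), oxidative burst at −0.18 in cluster 1 alone, and with members of 1 UMI or more attractants of monocytes and lymphocytes were at −0.11 and protumour genes at −0.14.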

Other observations

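No tests were run for this part, and its genes and values were chosen only after the result was seen. The genes that led the sgVC tumour-like clusters were far lower in the sgCPT1A library as a whole, without any naming of cells. Over all barcodes Wfdc2 stood at 1997 CPM in sgVC and 24.4 CPM in sgCPT1A, Tslp at 812 and 6.75 CPM, Hmga2 at 190.2 and 4.25 CPM, Krt8 at 541 and 85.1 CPM and Krt18 at 459.9 and 103.9 CPM. Epcam went the other way, at 3.80 and 38.3 CPM. Cluster 21 held 407 of the 592 sgVC Epcam UMIs in 13 cells and 1245 of the 1363 sgCPT1A Epcam UMIs in 30 cells. Within that cluster Epcam stood at 2279.5 and 1916.2 CPM, so the higher value of the whole sgCPT1A library came mostly from few cells. Those 30 cells also held 2874 of the 3026 Krt8 UMIs and 3482 of the 3693 Krt18 UMIs of the sgCPT1A library. Of the barcodes left out, 28 of 280 in sgVC and 11 of 455 in sgCPT1A were tumour-like by own markers.

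Ifnb1 was lower in the sgCPT1A library in monocyte/macrophage-like (−3.45, −3.85 to −3.09) and dendritic-like cells (−1.22, −1.60 to −0.86), where the type I interferon list was higher, though interferon-induced Cxcl9 and Cxcl10 were lower in the former. Ifnb1 was at −2.15 in the former without cells holding neutrophil UMIs, and at −0.40 in the latter by own markers. Within clusters of neutrophil-like cells, glycolysis genes were at −0.50 in cluster 0, −0.32 in cluster 1, −0.31 in cluster 2 and −0.27 in cluster 8, and NF-kB targets at 0.27, 0.45, 0.05 and 0.37. In the clusters made without the interferon genes glycolysis was at −0.09 (−0.44 to 0.18, which includes 0), −0.31, −0.48 and −0.49, and NF-kB targets were at 0.06, 0.52, 0.34 and 0.54. These medians were not set against the median gene of each cluster, which was −0.34 for the class as a whole. At Leiden resolution 2, B-like cells formed a class of their own, with 34 sgVC cells (0.365%, 0.253 to 0.509%) and 26 sgCPT1A cells (0.386%, 0.252 to 0.564%). In the main setting all kept cells had other class names, so these cells lay within other classes. Which classes held them was not determined, and gene ratios of those classes can include B-like cells.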
